A study of Homo sapiens with 18 samples.

How the data were processed

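Single-cell RNA was measured with a droplet method that counts the 3' ends of polyadenylated transcripts (a version 2 kit, per the labels' protocols). The material was UCLA1, an established human embryonic stem cell line, in 6 sublines. Per the labels, 3 sublines are controls (CTRL, lines CTRL1101, CTRL1106 and CTRL1109) and 3 carry a knockout of the catalytic domain of TET1 (CDKO, lines CDKO1102, CDKO1105 and CDKO1312). Each line was sampled at 3 stages: undifferentiated embryonic stem cells (hESC), incipient mesoderm-like cells (iMeLC) and aggregates at day 4 of germ cell induction (D4). That made 18 samples in 6 groups of 3, with 1 library per line and stage. The replicates of a group are separate lines, so the spread between them holds differences between lines as well as technical error. Each line number at 1 stage is the same line at the others. The labels give no date or batch.

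For each sample the authors deposited raw counts, whole numbers of unique molecular identifiers (UMIs) per gene and cell barcode, with no normalization. Per the submitters' processing notes, the tools were STAR 2.7, UMI-tools, Subread and featureCounts 2.0.1 on the genome build GRCh38. The gene annotation, the setting for strand and the rule that chose barcodes are not given in the sources used here. For 2 samples (CTRL iMeLC, lines CTRL1106 and CTRL1109) the deposited table held exactly 10000 barcodes, the largest number in any sample. Gene positions and types came from the GENCODE annotation of GRCh38; of 33527 genes in the tables, 31338 matched by symbol and 249 by identifier (94.2% in all). Because strand handling is not stated, counts of genes that overlap a gene on the opposite strand are uncertain, as are those of the near-identical metallothionein genes.

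A barcode was kept as a cell with at least 500 genes and under 20% mitochondrial UMIs, which kept 102652 of 122530 barcodes. Samples held 2395 to 9638 kept cells and 25.8 to 90.3 M UMIs. The median cell had 5367.5 to 26357 UMIs; mitochondrial genes took 4.27% to 8.10% of UMIs per cell on average and ribosomal protein genes 18.9% to 24.1% of all UMIs. Within a group each sample was counted as its own replicate, since each came from a line of its own. Counts of every pair of samples of a group differed by more than sampling noise (chi-square per gene 12.6 to 324). That shows spread between them and not that they are independent. Scrublet marked 0% to 4.38% of cells per sample as doublets, with thresholds that did not part the scores in most samples. No doublets were therefore removed in the main results. For shares of cells, removal of the 6% of cells with the highest scores was tried as an alternative. For gene tests the alternative removed only the cells marked by Scrublet. These were at most 0.113% of a sample's cells at hESC and iMeLC, so it tested little there.

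Cells are not replicates, so UMIs were summed over the kept cells of each sample. Sums were tested with edgeR's quasi-likelihood test (TMM factors, genes kept by filterByExpr with a minimum count of 10) and Benjamini-Hochberg adjustment over all genes tested; a gene was called at an adjusted p under 0.05. CDKO and CTRL were compared within each stage on 6 samples. Stages were compared within each genotype on 9 samples, and whether the stage change differed by genotype (the interaction) was tested on all 18 samples. Levels are given as counts per 1e6 UMIs (CPM), mean ± SD over 3 lines, and log2 fold changes ± SE. Where all libraries of a group held no UMI of a gene, the fold is a lower bound computed from a floor of 3 counts over the group. The stage comparisons and interactions were also fitted with the line as a replicate block, since the same line was sampled at each stage: deviations from the group mean correlated at 0.0223 to 0.5501 between 2 stages of the same line, and in 16 of 18 checks a sample correlated best with its own line.

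D4 cells (38124) were clustered together with Scanpy: counts scaled to 10000 per cell, log-transformed, 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 0.5, with no batch integration. The 16 clusters were named "X-like" from marker lists of 9 cell classes, when at least 3 markers of a class were 1.5-fold higher than in the other cells and detected in 10% of the cluster's cells. A name also required the share of the class's markers to lead that of the next class by at least 0.25, or a pair of classes to lead the others by as much and give both names; this margin was set after the clusters were seen. Shares of classes were compared with exact two-sided permutation tests over 3 against 3 lines, for which the smallest possible p is 0.10. Germ cells were also counted without clusters, as cells with a UMI of NANOS3 and of SOX17, TFAP2C or PRDM1, after each cell was thinned to 4500 UMIs. Shallower cells were left out: at D4 these were 120, 106 and 2594 cells of lines CTRL1101, CTRL1106 and CTRL1109, and 484, 325 and 59 cells of lines CDKO1102, CDKO1105 and CDKO1312. Between 343 and 2469 cells per sample were left out at the earlier stages. Within each D4 class, UMIs were summed per sample where at least 30 cells were present and tested as above. The hESC and iMeLC cells were clustered per stage in the same way after the gene results had been seen. There, a cluster whose HOX genes summed to at least 50 CPM and 5 times the level of the other clusters was called HOX-high, and a cluster that shared at least 5 of its 10 leading genes was called mixed.

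The 23 gene lists fixed before the data were examined covered core pluripotency, naive pluripotency, germ cell specification, germline genes silenced by methylation, primitive streak, definitive endoderm, amnion, mesoderm, neuroectoderm, endothelium and blood, fibroblasts, the DNA methylation machinery, imprinted genes, genes variably methylated among pluripotent lines, targets of BMP, WNT and NODAL, HOX genes, immediate early and heat shock genes, p53 targets, glycolysis and hypoxia, S phase, and G2 and M phase. Each list was tested with camera (preset correlation 0.01, and an estimated correlation as a check) and fry, both in limma on voom values. Also fixed before the data were examined were the groups, the tests, the cell class markers, most of the processing alternatives and the rule for naming genes. That rule took, per comparison of genotypes, the 10 higher and 10 lower called genes with the largest log2 fold change among those with a mean of at least 10 CPM and groups that did not overlap (5 each way within D4 classes, and for stage comparisons in CTRL). It added called members of the lists, the members with the smallest p, and 13 genes of the germline, of pluripotency and of DNA demethylation in every comparison. A gene outside it is said to have been chosen after its values were seen.

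Alternatives were DESeq2 in place of edgeR, its size factors in place of TMM, no filter on low counts, all barcodes, a stricter cell filter (1500 genes, 10% mitochondrial), all 18 samples in a single fit, thinning to the smallest sample, other clustering settings, and each replicate left out in turn. Removal of clusters of hESC and iMeLC cells was added after the data were seen. The fits were tested on simulated counts with 200 changed genes. At a 2-fold change 49.3% of changed genes were recovered for the genotypes at hESC, 49.3% at iMeLC and 2.99% at D4; at 4-fold 93.9%, 90.9% and 25.8%. For the interactions, 48.5% (iMeLC against hESC) and 34.8% (D4 against iMeLC) were recovered at 4-fold. In the same simulations 13 of 131 calls for the genotypes at hESC were false, 11 of 121 at iMeLC and 2 of 21 at D4. For the interactions 2 of 43 (iMeLC against hESC) and 2 of 27 (D4 against iMeLC) were false. At hESC and iMeLC the share of false calls was thus above that set by the threshold for calling a gene. Camera recovered 20 of 20 shifted lists and called none of the unshifted lists. Genes were simulated independently of each other, so this could not show how camera treats lists whose genes move together. The tools were Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, Scanpy 1.11.5, scikit-learn 1.9.0, leidenalg 0.10.2, python-igraph 0.11.9, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. XIST and Y-linked genes were left out of the named genes.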

Results

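TET1 is a dioxygenase that oxidises 5-methylcytosine in DNA. The series compared human embryonic stem cells without its catalytic domain with control cells on the way to human primordial germ cell-like cells (hPGCLC). Transcripts were counted cell by cell in 3 CTRL and 3 CDKO lines of UCLA1 at 3 stages, hESC, iMeLC and D4, with 1 library per line and stage. Kept cells numbered 102652, and the depth of a library ran from 25.8 M UMIs (M, 1e6; a CDKO hESC library) to 90.3 M (a CTRL D4 library). CTRL and CDKO libraries held 47.8 ± 10.0 and 33.5 ± 7.80 M UMIs at hESC (SD, n = 3 lines each). They held 65.0 ± 2.84 and 47.2 ± 9.32 M at iMeLC, and 77.7 ± 11.7 and 73.4 ± 7.66 M at D4. The share of barcodes that passed as cells was lower in CDKO than in CTRL at hESC (61.5 ± 8.41% against 81.7 ± 4.32%) and at iMeLC (77.7 ± 12% against 90.9 ± 4.05%), and close at D4 (94.8 ± 1.19% against 96.4 ± 1.27%). The CTRL iMeLC library of CTRL1101 stood apart, with 2395 cells at a median of 26357 UMIs. CTRL1109 stood apart at every stage on chromosome 12: 75 genes in the first 30 Mb had a median log2 difference from the other lines of 0.72 at hESC, 0.81 at iMeLC and 0.77 at D4, while the other 284 genes of that chromosome had medians of -0.10, -0.01 and -0.04. Among all tested genes of that region, 12 of 249 were called lower and 1 higher in CDKO at hESC, 5 and 1 of 236 at iMeLC, and 0 of 284 at D4 (edgeR).

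**Figure D1:**
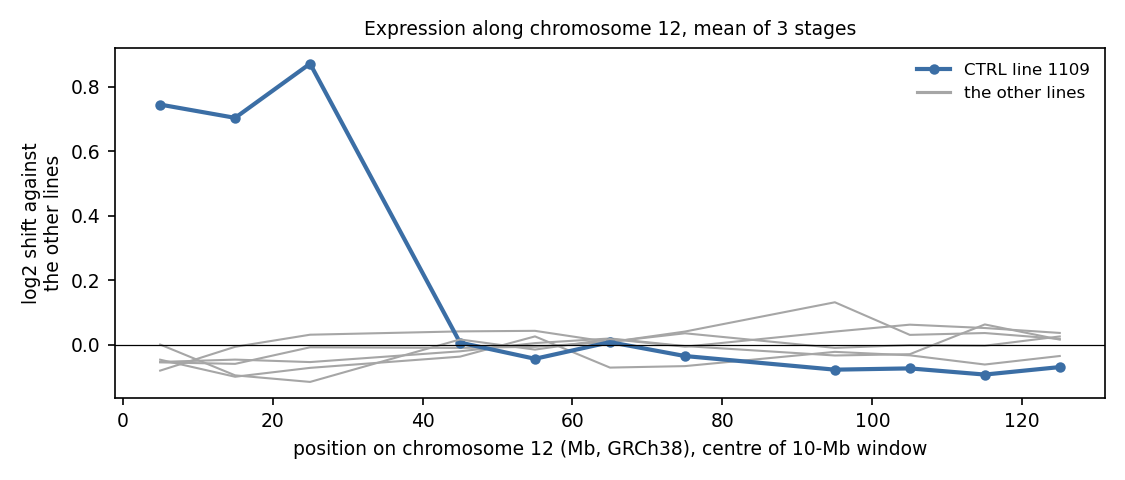
Mean log2 difference of each line from the other lines along chromosome 12 (x axis: centre of 10-Mb windows in Mb, GRCh38; y axis: log2, mean of 3 stages; windows with under 15 genes are not drawn). CTRL1109 (blue) lies well above 0 in the first 3 windows and near 0 in the rest, where the other lines (grey) lie throughout.

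TET1 itself (chromosome 10, 68560656 to 68694482, plus strand) was counted in every library. In lines CTRL1101, CTRL1106 and CTRL1109 TET1 had 10656, 12215 and 8134 UMIs at hESC, 8646, 10267 and 11342 at iMeLC, and 11809, 8940 and 8634 at D4. In lines CDKO1102, CDKO1105 and CDKO1312 TET1 had 8254, 7139 and 5752 UMIs at hESC, 11359, 7778 and 9181 at iMeLC, and 12428, 13818 and 13554 at D4. TET1 was at 214 ± 19.1 CPM in CTRL and 216 ± 11.3 CPM in CDKO at hESC (log2 fold change 0.02 ± 0.08, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.928). The levels were 155 ± 21.8 and 201 ± 4.16 CPM at iMeLC (0.37 ± 0.11, adjusted p = 0.165) and 130 ± 24.9 and 179 ± 17.8 CPM at D4 (0.46 ± 0.17, adjusted p = 0.553). Counts of 3' ends outside the deleted part check nothing about the knockout, and the position of the deletion is not given in the sources used here. Its relatives TET2 and TET3 did not pass the test at hESC either (0.33 ± 0.17, adjusted p = 0.262, and 0.13 ± 0.14, adjusted p = 0.571).

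The first comparison asked what the missing catalytic domain changed before any differentiation. At hESC a set of genes was lower in the 3 CDKO lines, and some of them were almost silent. NNAT, an imprinted gene of neuronal development, fell from 15.9 ± 0.302 CPM in CTRL to 0.251 ± 0.0594 CPM in CDKO (log2 fold change -6.00 ± 0.17, adjusted p = 5.74e-06, n = 3 lines each, edgeR quasi-likelihood test throughout). The metallothioneins MT1H and MT1G, which bind zinc and copper, fell from 46.9 ± 15.3 to 0.112 ± 0.0686 CPM (-8.56 ± 0.40, adjusted p = 9.69e-05) and from 110 ± 26.7 to 3.32 ± 0.735 CPM (-5.02 ± 0.23, adjusted p = 9.69e-05). Reads of such near-identical genes may be divided among them, so each value is uncertain. SERPINB1, an inhibitor of neutrophil proteases, fell from 22.9 ± 4.09 to 1.59 ± 1.32 CPM (-3.93 ± 0.46, adjusted p = 0.00564). LGALS1, which encodes galectin-1, fell from 164 ± 82.9 to 40.1 ± 20.1 CPM (-2.02 ± 0.43, adjusted p = 0.0383). The other genes named by the rule among those that fell were SYNE4 (-2.33), TNNC2 (-2.21), the collagen gene COL7A1 (-1.96), the lactate transporter gene SLC16A3 (-1.95), RINL (-1.57) and MIB2 (-1.28). In GRCh38, NNAT lies on chromosome 20 (37521206 to 37523693, plus strand, overlapped by BLCAP on the opposite strand), MT1G on chromosome 16 (56666731 to 56668065, minus strand) next to MT1H (56669814 to 56671129, plus strand), SERPINB1 on chromosome 6 (2832332 to 2842006) and LGALS1 on chromosome 22 (37675608 to 37679806).

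Other genes rose in the same hESC samples. The long non-coding RNA AC104257.1 (chromosome 8, 131308545 to 131317632) rose from 9.11 ± 3.55 to 89.0 ± 17 CPM (3.29 ± 0.27, adjusted p = 0.00133). The apolipoprotein gene APOA2 rose from 3.59 ± 1.24 to 23.4 ± 15.1 CPM (2.7 ± 0.52, adjusted p = 0.0293). CER1, a secreted antagonist of NODAL and BMP made in endoderm (chromosome 9, 14719724 to 14722717), rose from 65.0 ± 11.6 to 283 ± 131 CPM (2.13 ± 0.30, adjusted p = 0.0116). S100A6, a calcium-binding protein gene, rose from 368 ± 100 CPM by 2.12 ± 0.20 (adjusted p = 0.00211), and the natriuretic peptide gene NPPB from 43.6 ± 5.17 to 171 ± 72.4 CPM (1.97 ± 0.29, adjusted p = 0.0128). The rule also named PCAT14 (2.27), AC027288.1 (2.09), ABALON (1.96, antisense to BCL2L1 and therefore uncertain), COLEC12 (1.92) and ANKRD1 (1.91). S100A6 (41252 CPM against 160 CPM in the other clusters) and ABALON (694 against 1.88 CPM) were leading genes of the HOX-high hESC cluster. The share of that cluster is given below. In all, 557 genes rose and 551 fell of 18844 tested, and the median log2 fold change of all genes was -0.02.

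By gene list, 7 of 14 measured definitive endoderm genes rose and none fell at hESC, among them FOXA2 (1.75 ± 0.35), GATA6 (1.61 ± 0.33), CXCR4 (1.73) and SOX17 (1.47 ± 0.32, adjusted p = 0.0395); 11 passed when adjusted over the list alone. The list was called by camera (adjusted p = 8.37e-07, but 0.343 as an adjusted p with an estimated correlation). Of 12 mesoderm genes 6 rose, with GATA4 (1.88 ± 0.43), HAND2 (1.82 ± 0.27), MEIS2 (1.43 ± 0.18) and BMP4 (0.66 ± 0.09) among them (9 adjusted over the list alone; adjusted p = 6.56e-06, and adjusted p = 0.0947 with an estimated correlation). Among 10 NODAL targets 3 rose, among them CER1 and NODAL itself (60.7 ± 17.9 to 136 ± 33.5 CPM, 1.16 ± 0.24; 8 adjusted over the list alone; adjusted p = 4.14e-05, and adjusted p = 0.0947 with an estimated correlation). Of 15 primitive streak genes FGF8 rose (1.47 ± 0.27) and TBX6 fell (-1.27 ± 0.17). EOMES (1.45 ± 0.36, adjusted p = 0.0549), MIXL1 (1.89 ± 0.48, adjusted p = 0.0571) and TBXT (1.67 ± 0.78, adjusted p = 0.218) did not pass. In that list 6 were higher and 2 lower adjusted over the list alone (adjusted p = 0.0291, and adjusted p = 0.646 with an estimated correlation). One amnion gene of 12, NR2F2, rose (1.56 ± 0.14; 2 adjusted over the list alone; adjusted p = 0.0135, and adjusted p = 0.230 with an estimated correlation). Definitive endoderm-like cells, defined by clustering, made up 2.63 ± 0.59% of CTRL and 8.34 ± 3.77% of CDKO hESC (exact two-sided permutation test, p = 0.10, the smallest that 3 against 3 lines allow); with called genes left out of the clustering the shares were 2.32 ± 0.56% and 7.20 ± 3.15%. That hESC cluster carried primitive streak markers too. Without the HOX-high, mixed and endoderm-like clusters, 1 of 12 endoderm genes stayed called, APOA2 was at 1.23 (adjusted p = 0.139), SOX17 at 0.59 (adjusted p = 0.360), FOXA2 at 1.08 and CER1 at 2.0 (adjusted p = 0.0161). Of the mesoderm genes BMP4 alone stayed called without the HOX-high cluster, where MEIS2 was at 1.11 ± 0.35 (adjusted p = 0.105) and HAND2 at 1.77 ± 0.48 (adjusted p = 0.0728), the latter with little change in fold and a wider spread. Without all 3 clusters HAND2 and COL3A1 had too few counts for a test, MEIS2 was at 0.42 ± 0.40 (adjusted p = 0.558) and GATA4 at 1.24 ± 0.65 (adjusted p = 0.288), and the list median went from 0.90 to 0.51 (adjusted p = 0.0819 by camera). The camera calls of 4 more lists ended there with smaller medians: endoderm (1.46 to 0.64, adjusted p = 0.0545), primitive streak (1.33 to 0.74, adjusted p = 0.255), amnion (0.39 to 0.22, adjusted p = 0.182) and WNT targets (0.31 to 0.12, adjusted p = 0.255). NR2F2 was at 0.60 ± 0.28 (adjusted p = 0.233).

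HOX genes, which pattern the body axis and are kept low in pluripotent cells, rose together at hESC. Of 18 measured, 12 passed the test and none fell (15 adjusted over the list alone). Examples were HOXC10 at 1.93 ± 0.18, HOXB9 at 1.80 ± 0.18 and HOXC8 at 1.73 ± 0.21, each under 4 CPM in both genotypes. The list had a median of 1.62 and was called by camera (adjusted p = 5.74e-11, and adjusted p = 0.0947 with an estimated correlation). A cluster of 2504 hESC cells held 47.4% of all HOX UMIs at this stage. Its cells had a median of 947 UMIs against 6565 in the other clusters. Among its leading genes were PRRX1, S100A6 (41252 CPM against 160 CPM), CRYAB, HIST3H2A, NR2F2, ABALON and H3F3C. This HOX-high cluster made up 4.85 ± 0.98% of CTRL and 12.6 ± 7.44% of CDKO hESC (exact permutation p = 0.30), and a further cluster that shared its leading genes 6.05 ± 3.19% and 14.2 ± 4.19% (p = 0.10). Without both clusters only 4 HOX genes had enough counts to be measured and none was called. The list median was 1.12 (adjusted p = 0.282 by camera), HOXC8 was at 1.95 (adjusted p = 0.0666; 1.73 ± 0.21 in all cells), and summed HOX levels were 2.23 ± 0.78 CPM in CTRL and 8.40 ± 8.87 CPM in CDKO (7.86 ± 1.43 and 25.7 ± 6.07 CPM in all cells). S100A6 was at 1.36 (adjusted p = 0.154), and 312 of the 557 genes that rose and 382 of the 551 that fell were still called.

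**Figure D2:**
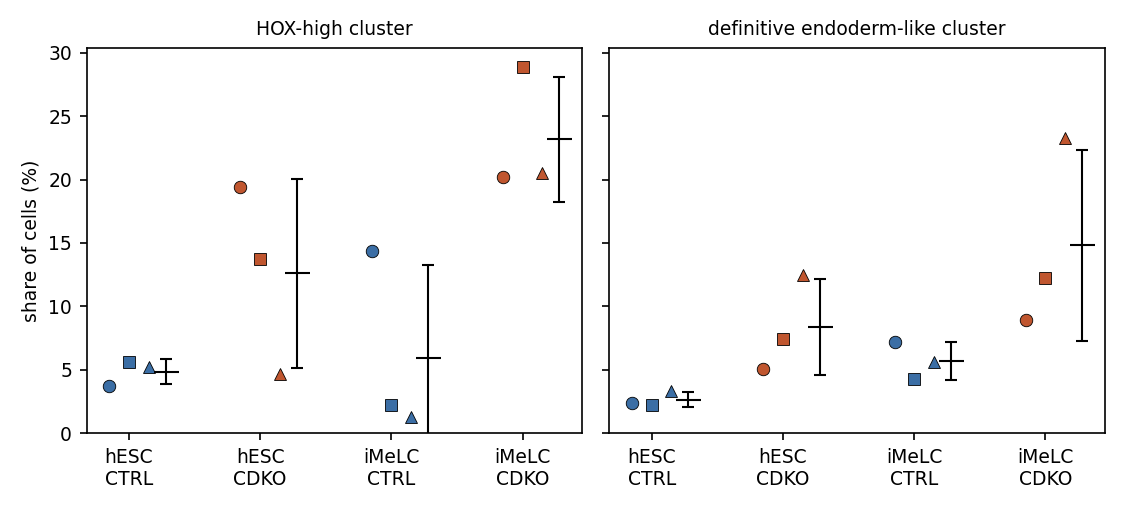
Share of cells (y axis, %) of each line in the HOX-high cluster (left) and the definitive endoderm-like cluster (right) at hESC and iMeLC. Points are lines (blue, CTRL; orange, CDKO), bars mean ± SD of 3 lines, with a bar that would pass below 0 drawn to 0. In the right panel the CDKO lines lie above the CTRL lines at both stages; in the left panel they overlap at hESC.

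Germ cell genes moved both ways at hESC. Of 15 measured genes of germ cell specification 4 rose, namely SOX17, PRDM1 (3.88 ± 0.952 to 9.23 ± 3.30 CPM, 1.25 ± 0.28, adjusted p = 0.0415), KLF4 (1.12 ± 0.16) and ARID5B (1.19 ± 0.18), also 4 when adjusted over the list alone (list adjusted p = 0.0685). TFAP2C (0.45 ± 0.18, adjusted p = 0.154) and NANOS3 (0.25 ± 0.39, adjusted p = 0.716) did not pass. Without the HOX-high, mixed and endoderm-like clusters none of the 15 stayed called, with PRDM1 at 0.25 ± 0.33 (adjusted p = 0.674), KLF4 at 0.39 ± 0.16 (adjusted p = 0.193) and ARID5B at 0.61 ± 0.28 (adjusted p = 0.229). Of 9 germline genes known to be silenced by DNA methylation in other cells, the piRNA pathway genes PIWIL2 (6.71 ± 1.2 to 0.696 ± 0.125 CPM, -3.25 ± 0.22, adjusted p = 0.000378) and TDRD1 (-4.69 ± 0.60) fell, and 3 fell adjusted over the list alone (list adjusted p = 0.121). Of 16 imprinted genes 4 fell (NNAT, NAP1L5 at -4.58 ± 0.39, L3MBTL1 at -0.68 ± 0.14 and KCNQ1OT1 at -0.62 ± 0.13); adjusted over the list alone, 3 were higher and 4 lower (list adjusted p = 0.285). Among 12 genes that vary in methylation between pluripotent lines, TSPYL5 was at least 257-fold lower, from 7.42 ± 3.30 CPM to no UMI in any CDKO line, and DNAJC15 rose (0.45 ± 0.10), the same pair adjusted over the list alone (list median -0.04, mean -0.92, camera direction up, adjusted p = 0.743). None of 12 genes of the DNA methylation machinery passed (adjusted p = 0.223; 0 adjusted over the list alone).

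Pluripotency genes stayed close to CTRL. POU5F1 had 742 ± 58.2 CPM in CTRL and 746 ± 115 CPM in CDKO (0.01 ± 0.12, adjusted p = 0.975), SOX2 was at -0.02 ± 0.11 (adjusted p = 0.917) and NANOG at -0.08 ± 0.15 (adjusted p = 0.771). Of 20 core pluripotency genes DPPA4 alone passed (-0.34 ± 0.07; also 1 adjusted over the list alone; list adjusted p = 0.695), and of 9 naive pluripotency genes KLF4 (list median -0.17, mean 0.17, camera direction up, adjusted p = 0.651). Of 20 glycolysis and hypoxia genes 6 fell, such as BNIP3 (166 ± 45.7 to 79.5 ± 1.95 CPM, -1.06 ± 0.18), PFKFB4 (-0.86 ± 0.13) and PGK1 (-0.56 ± 0.12). ADM (0.83 ± 0.20) and VEGFA (0.47 ± 0.11) rose (2 higher and 9 lower adjusted over the list alone; adjusted p = 0.000592, and adjusted p = 0.383 with an estimated correlation). Of 12 immediate early and heat shock genes, which respond to handling of cells, 5 rose, among them FOS (1.56 ± 0.33) and JUN (1.06 ± 0.16) (8 adjusted over the list alone; adjusted p = 0.000356, and adjusted p = 0.343 with an estimated correlation). ID1 fell (-0.45 ± 0.08) as the sole called member of 10 BMP targets (3 higher and 1 lower adjusted over the list alone; adjusted p = 0.450). No WNT target of 12 passed (list median 0.31, adjusted p = 0.0343, and adjusted p = 0.629 with an estimated correlation). Among fibroblast genes COL3A1 (1.22 ± 0.24) and TAGLN (0.82 ± 0.18) of 10 rose (list adjusted p = 0.165). Among endothelial and blood genes SOX18 of 6 rose (list median -0.16, mean 0.07, camera direction down, adjusted p = 0.807). None passed among 9 neuroectoderm genes (adjusted p = 0.695), 15 p53 targets (adjusted p = 0.831), 39 S phase genes (adjusted p = 0.450) and 49 G2 and M phase genes (adjusted p = 0.651). Of the 9 marker sets used to name clusters, camera called those of primitive streak (adjusted p = 3.1e-05), definitive endoderm (0.000212) and mesoderm (0.00231) higher, each at an adjusted p = 0.343 with an estimated correlation. The other 6 were not called: hPGCLC (adjusted p = 0.137), fibroblast (0.155), amnion (0.382), neuroectoderm (0.843), endothelial or blood (0.855) and pluripotent (0.999). None of the camera calls at any stage held with an estimated correlation.

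At hESC the count of 1108 called genes was 2016 with DESeq2 and 196 with all 18 samples in a single fit. It was 337 without CTRL1106, 608 without CDKO1102, 182 without CDKO1105 and 274 without CDKO1312.

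The same question was asked of iMeLC, the state from which germ cell induction starts. NNAT, MT1H, MT1G and LGALS1 were lower in CDKO here too. NNAT fell from 20.8 ± 2.37 to 0.117 ± 0.0375 CPM (-7.49 ± 0.21, edgeR adjusted p = 1.27e-05). MT1H fell from 222 ± 109 to 1.72 ± 0.502 CPM (-7.00 ± 0.50, adjusted p = 0.00101). MT1G fell from 269 ± 81.6 to 11.1 ± 4.45 CPM (-4.60 ± 0.35, adjusted p = 0.00125), and LGALS1 from 135 ± 65.6 to 19.5 ± 6.95 CPM (-2.78 ± 0.37, adjusted p = 0.0181). CCK, which encodes the peptide cholecystokinin, fell from 24.9 ± 8.98 to 0.273 ± 0.0872 CPM (-6.55 ± 0.38, adjusted p = 0.000371) and CST6, a cystatin gene, from 18.9 ± 3.99 to 1.43 ± 0.459 CPM (-3.74 ± 0.26, adjusted p = 0.000872). The rule also named COL7A1 (-2.40), PCOLCE (-0.93), the DNA repair gene RAD51C (-0.91) and SDCCAG8 (-0.80) among those that fell. Among the genes that rose were MIXL1 (10.4 ± 3.57 to 40.7 ± 17.1 CPM, 1.97 ± 0.34, adjusted p = 0.0463) and GATA6 (8.56 ± 2.72 to 29.4 ± 10.1 CPM, 1.78 ± 0.31, adjusted p = 0.0458). The rule further named AC104257.1 (2.92), MYL4 (2.85), AC027288.1 (2.44), APOA2 (2.32), PRRX1 (2.06), FGF17 (1.64) and AC108052.1 (1.45).

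At iMeLC 76 genes rose and 144 fell of 18591 tested, with a median of -0.01 over all genes. Of the genes tested at both stages, 33 rose and 118 fell at both, against 2.32 and 3.85 for independent lists, and none went opposite ways. The lists were not independent, since the same 6 lines were sampled at both stages and deviations of a line from its group correlated between them (r = 0.251 to 0.550), so line differences alone can give shared calls. The interaction, which tests whether the change between these stages differed by genotype, called 0 of 21935 genes with edgeR (897 at an unadjusted p under 0.05) and 15 with DESeq2. By list, 12 of 14 endoderm genes were higher adjusted over the list alone and GATA6 over all genes (camera adjusted p = 3.78e-10, and adjusted p = 0.223 with an estimated correlation). Of 17 primitive streak genes 7 were higher in that way, with FGF8 (1.21 ± 0.18) and MIXL1 over all genes (adjusted p = 5.59e-05, and adjusted p = 0.321 with an estimated correlation). None of 20 HOX genes passed over all genes and 17 adjusted over the list alone (median 1.61, adjusted p = 1.11e-10, and adjusted p = 0.223 with an estimated correlation). For 13 mesoderm genes the counts were 0 and 7 (adjusted p = 9.59e-06), and for 10 NODAL targets 1 and 5 (adjusted p = 3.9e-06), both with an adjusted p = 0.223 with an estimated correlation. WNT targets had 0 and 4 of 12 (adjusted p = 0.000722, and adjusted p = 0.321 with an estimated correlation). Of 9 methylation-silenced germline genes PIWIL2 (-4.24 ± 0.30) and TDRD1 (at least 18.4-fold lower) fell (1 higher and 2 lower adjusted over the list alone; adjusted p = 0.0213, and adjusted p = 0.223 with an estimated correlation). Germ cell specification had 0 of 13 over all genes, with 4 higher and 1 lower adjusted over the list alone (median 0.64, adjusted p = 0.0165, and adjusted p = 0.223 with an estimated correlation), and SOX17 was at 1.53 ± 0.35 (adjusted p = 0.0972). NAP1L5 (-6.46 ± 0.40) and NNAT were the called imprinted genes of 17, and TSPYL5 (at least 480-fold lower) the called variably methylated gene of 11. IDH1 (0.50 ± 0.08) was the called gene of the DNA methylation machinery, HSPA1A (-1.55 ± 0.24) that of the stress genes and CA9 (-1.43 ± 0.24) that of glycolysis and hypoxia. Camera also called the naive pluripotency (adjusted p = 0.0225), amnion (adjusted p = 0.0175), p53 (adjusted p = 0.0129) and, lower, G2 and M phase lists (adjusted p = 0.00844), with no member called over all genes and adjusted p values of 0.223, 0.261, 0.489 and 0.489 with an estimated correlation.

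HOX-high cells made up 5.96 ± 7.29% of CTRL and 23.2 ± 4.94% of CDKO iMeLC, and definitive endoderm-like cells 5.70 ± 1.47% and 14.8 ± 7.56% (exact permutation p = 0.10 for both). With called genes left out of the clustering the shares were 6.77 ± 6.89% and 24.3 ± 5.60%, and 5.51 ± 1.52% and 14.1 ± 7.02%. The HOX list's median of 1.61 went to 0.45 without the HOX-high cluster (14 genes measured, adjusted p = 0.0561 by camera) and to 0.13 without the mixed cluster too (11 genes, adjusted p = 0.239). Without the HOX-high, mixed and endoderm-like clusters 34 of the 76 genes that rose and 119 of the 144 that fell were still called, and FGF17 (-0.69), GATA6 (-0.05) and PRRX1 (-0.29) turned direction. Camera calls ended there for HOX genes (adjusted p = 0.396) and 6 more lists, all with medians closer to 0. These were endoderm (1.23 to 0.05, adjusted p = 0.356), mesoderm (0.65 to 0.11, adjusted p = 0.482), germ cell specification (0.64 to 0.07, adjusted p = 0.482), naive pluripotency (0.54 to 0.31, adjusted p = 0.0568), amnion (0.46 to -0.12, adjusted p = 0.926) and G2 and M phase (-0.08 to -0.03, adjusted p = 0.225). The count of 220 was 956 with DESeq2 and 494 without the filter on low counts, and 106, 60 and 67 without CTRL1106, CDKO1105 and CDKO1312.

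At D4 the comparison asked how many cells took the germ cell fate. hPGCLC-like cells were fewer in every CDKO line than in every CTRL line. Cluster 7, with 2245 cells led by ACTG2, NANOS3 and TCL1A, was the only cluster named hPGCLC-like. It held 8.60%, 5.23% and 12.9% of the cells of lines CTRL1101, CTRL1106 and CTRL1109 (8.89 ± 3.82%) and 1.48%, 2.25% and 0.563% of lines CDKO1102, CDKO1105 and CDKO1312 (1.43 ± 0.85%), a 6.21-fold difference of means (exact two-sided permutation p = 0.10, the smallest possible here). With called genes left out of the clustering the shares were 8.83 ± 3.77% and 1.45 ± 0.85%. Counts without clusters gave the same order at D4. Cells with NANOS3, an RNA-binding regulator of germ cells, and SOX17, TFAP2C or PRDM1 made up 5.85 ± 1.91% in CTRL and 1.02 ± 0.51% in CDKO after thinning to 4500 UMIs (exact permutation p = 0.10), and 9.81 ± 1.73% and 2.12 ± 0.64% without thinning. Cells below that depth, 2594 in CTRL1109 and 59 to 484 in the other lines, were left out of the thinned count. Measured in the same way, the shares were 0.00581% and 0.0227% at hESC and 0.060% and 0.0879% at iMeLC. Cells with at least 2 of SOX17, TFAP2C and PRDM1, whether or not NANOS3 was found, made up 7.98 ± 1.74% of CTRL and 3.72 ± 0.50% of CDKO at D4, a smaller difference. By that rule the CDKO shares were the higher ones at hESC (0.546% and 1.86%) and iMeLC (0.737% and 2.06%), with an exact permutation p = 0.10 at each stage. SOX17 and PRDM1 are also in the definitive endoderm list, so that rule can count endoderm-like cells. The mean share of endoderm-like cells was higher in CDKO at each stage. NANOS3 was found in 58.2% of CTRL and 51.3% of CDKO hPGCLC-like cells but in 1.13% and 0.878% of amnion-like cells, all thinned to that depth. In the other named classes it was found in 0.617% to 3.17% of CTRL and 0.191% to 0.535% of CDKO cells. Among cells without a name it was found in 21.9% of CTRL and 1.97% of CDKO cells of cluster 10, 16.5% and 5.43% of cluster 13, and at most 2.60% of the rest. Unnamed cluster 10, also led by ACTG2, NANOS3 and TCL1A but with too few germ cell markers for the name, held 3.92% of CTRL and 2.81% of CDKO cells (exact permutation p = 0.70).

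**Figure D3:**
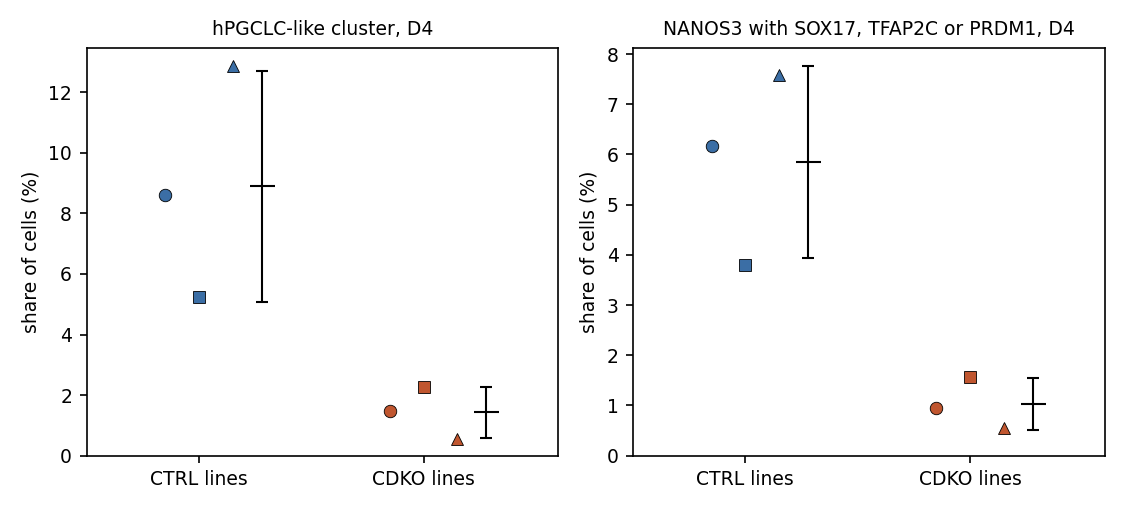
Share of D4 cells (y axis, %) per line in the hPGCLC-like cluster (left) and with a UMI of NANOS3 and of SOX17, TFAP2C or PRDM1 after thinning (right). Points are lines, bars mean ± SD of 3 lines; the 3 CTRL lines (blue) lie above the 3 CDKO lines (orange) in both panels.

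The other D4 classes varied more between lines. Definitive endoderm-like cells made up 3.37 ± 1.54% of CTRL and 12.9 ± 8.33% of CDKO cells without overlap of the lines (exact p = 0.10, Benjamini-Hochberg adjusted p = 0.40 over the other classes). On average cluster 11 held most of them in CTRL (2.06% of cells) and cluster 8 in CDKO (7.5%). The latter came mainly from CDKO1102, where cluster 8 held 21%, while cluster 11 led in CDKO1105 (4.46%) and CDKO1312 (10.8%). Pluripotent-like cells made up 1.08 ± 1.39% and 14.2 ± 11.7% (exact permutation p = 0.20, adjusted p = 0.40). Amnion-like cells made up 30.8 ± 23% and 11.8 ± 4.09% (exact permutation p = 0.20, adjusted p = 0.40), and fibroblast and mesoderm-like cells 25.2 ± 27.8% and 8.76 ± 6.66% (p = 0.60, adjusted p = 0.72). Of the last, cluster 0 held most in CTRL (53.8% of the cells of CTRL1109) and cluster 9 most in CDKO. Pluripotent and primitive streak-like cells made up 5.36 ± 7.20% and 10.7 ± 14%, primitive streak-like cells 7.47 ± 6.69% and 7.12 ± 9.99%, and unnamed clusters 17.8 ± 5.49% and 33.1 ± 18.8%. The order of the fibroblast and mesoderm-like shares turned with fewer variable genes and with all barcodes, and that of the primitive streak-like shares with a coarser clustering and a stricter cell filter. That of the unnamed clusters (CDKO minus CTRL 15.3 points) turned to -5.17 points with a coarser clustering, -1.13 with all barcodes and -4.42 with doublet calls of Scrublet removed. The difference in pluripotent-like cells, 13.1 points here, was 21.2 to 23.2 points without overlap of the lines (exact permutation p = 0.10) in those 3 settings and with called genes left out of the clustering.

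Summed over all D4 cells, 7 genes fell in CDKO and none rose of 20715 tested with edgeR (1773 at an unadjusted p under 0.05; DESeq2 called 219 higher and 278 lower). NNAT fell from 29.5 ± 10.1 to 0.0595 ± 0.0408 CPM (-8.87 ± 0.57, adjusted p = 0.0107) and MT1G from 58.4 ± 17.4 to 0.669 ± 0.235 CPM (-6.44 ± 0.40, adjusted p = 0.0107). The imprinted gene NAP1L5 also fell (-8.19 ± 0.63, adjusted p = 0.0226), as did 4 genes outside the rule, named after their values were seen: TCL1A, an activator of AKT kinases (-7.77 ± 0.44), the chaperone gene DNAJA4 (-7.53 ± 0.42), NPFFR2 (-4.85 ± 0.37) and SMIM10 (-8.59 ± 0.76). All 7 had also fallen at hESC and at iMeLC, against 0.194 and 0.0509 for independent lists, which those from the same lines were not. Germ cell genes did not pass over all D4 cells: NANOS3 (chromosome 19, 13862063 to 13880757) had 35.0 ± 19.6 CPM in CTRL and 4.69 ± 2.31 CPM in CDKO (-2.90 ± 0.55, adjusted p = 0.319). TFAP2C was at -0.93 ± 0.69 (adjusted p = 0.753), PRDM1 at -0.57 ± 0.25 (adjusted p = 0.603) and SOX17 at -0.42 ± 0.42 (adjusted p = 0.822). SOX2 had 8.60 ± 11.1 and 99.9 ± 68.0 CPM (3.54 ± 1.24, adjusted p = 0.538). In simulated data of this depth and spread, 25.8% of 4-fold changes were recovered.

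Of the gene lists at D4, imprinted genes had 2 of 19 members lower (adjusted p = 0.0156, and adjusted p = 0.347 with an estimated correlation) and no other list had a called member. Germ cell specification was called lower by camera (16 genes, median -0.72, 1 lower adjusted over the list alone; adjusted p = 0.00222, and adjusted p = 0.347 with an estimated correlation). So were amnion genes (18 genes, median -0.95; adjusted p = 1.31e-05, and 0.469 as an adjusted p with an estimated correlation). HOX genes were lower as well (26 genes, median -0.76; adjusted p = 1.04e-05, and adjusted p = 0.469 with an estimated correlation), and so were BMP targets (median -0.51; adjusted p = 0.000864, and adjusted p = 0.347 with an estimated correlation). Mesoderm (adjusted p = 0.00174), endothelial and blood (0.00166) and fibroblast lists (0.0161) were lower too, with adjusted p values of 0.673, 0.347 and 0.673 with an estimated correlation. Core pluripotency (20 genes, median 0.91; adjusted p = 0.000436) and definitive endoderm (adjusted p = 0.0161) were called higher, both at an adjusted p = 0.673 with an estimated correlation. The germ cell, amnion, mesoderm, fibroblast, pluripotency and endoderm lists belong to cell types whose mean shares at D4 differed in the same direction. Of these shares, only those of hPGCLC-like and definitive endoderm-like cells did not overlap between CTRL and CDKO lines. The order of the fibroblast and mesoderm-like shares turned in some settings. Whether shares account for the list calls was not tested. The count of 7 was 732 with all 18 samples in a single fit. It was 17 without CTRL1106, 4 without CDKO1312 and 0 without CTRL1101, CDKO1102 or CDKO1105.

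**Figure D4:**
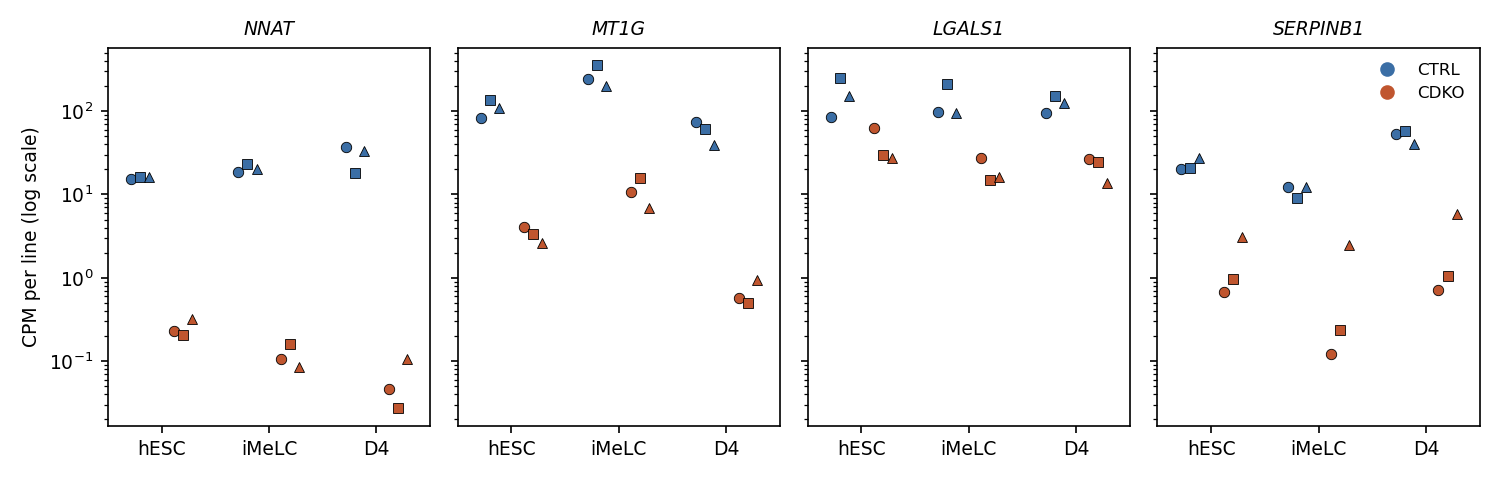
CPM per line (y axis, log scale) of NNAT, MT1G, LGALS1 and SERPINB1 at the 3 stages (blue, CTRL; orange, CDKO; each point is a line). Every CDKO line lies below every CTRL line in each panel and stage; LGALS1 at D4 (-2.52 ± 0.31, adjusted p = 0.128) and SERPINB1 at iMeLC (-3.59 ± 0.83, adjusted p = 0.101) and D4 (-4.30 ± 0.86, adjusted p = 0.319) did not pass the test.

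Within D4 classes the comparison asked which genes differed among cells of the same name. The amnion-like, the endoderm-like and the fibroblast and mesoderm-like class each joined 2 clusters with unequal shares, so there shares of clusters were not kept apart from changes within cells. In hPGCLC-like cells (3 CTRL and 2 CDKO lines with enough cells) the germ cell regulators did not pass. They were among the markers that named the class, and 22.4% of simulated 2-fold changes were recovered here, so a change in them was not excluded. NANOS3 had 335 CPM in CTRL and 226 CPM in CDKO (-0.56, adjusted p = 0.95), while SOX17 was at -0.11, TFAP2C at 0.10 and PRDM1 at -0.23. 3 of 12228 genes fell there and none rose. In data simulated for this class, 11 of 75 calls were false. TCL1A (chromosome 14, 95709967 to 95714196), itself a leading gene of the cluster, fell from 207 ± 43.3 to 2.14 ± 1.55 CPM (-6.48 ± 0.41, adjusted p = 0.000288). LGALS1 fell from 357 ± 98.0 to 49.7 ± 19.9 CPM (-2.86 ± 0.33, adjusted p = 0.0262) and SERPINB1 from 28.4 ± 3.19 CPM to no UMI, at least 20.4-fold lower. NNAT fell in the other 5 classes tested: at -8.99 ± 0.64 in amnion-like, -7.85 ± 0.39 in pluripotent and primitive streak-like and -8.38 ± 0.38 in primitive streak-like cells, and to no UMI in definitive endoderm-like (at least 197-fold lower) and fibroblast and mesoderm-like cells (at least 294-fold lower). MT1G fell in amnion-like (-5.40 ± 0.55), endoderm-like (-5.35 ± 0.52) and primitive streak-like cells (-7.19 ± 0.50).

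In all, 5 genes were called in amnion-like, 5 in endoderm-like, 30 in fibroblast and mesoderm-like, 15 in pluripotent and primitive streak-like (2 CTRL and 3 CDKO lines) and 13 in primitive streak-like cells (also 2 and 3 lines), while pluripotent-like cells had too few CTRL cells for a test. In endoderm-like cells the metallothionein MT2A rose (1.57 ± 0.16) and DCDC2 (-3.36 ± 0.38) fell. In fibroblast and mesoderm-like cells SOD3 (2.22 ± 0.22), MT1F (2.12 ± 0.18), FOS (1.73 ± 0.24), AC073174.1 (1.62 ± 0.20) and PDLIM1 (1.53 ± 0.14) rose. SERPINB1 (-5.07 ± 0.60), CYB5D1 (-2.66 ± 0.27), the neuropeptide gene NPY (-2.22 ± 0.27) and HOXB-AS3 (-2.21 ± 0.28) fell there. On average this class came mainly from different clusters in CTRL (cluster 0) and CDKO (cluster 9). In pluripotent and primitive streak-like cells NLRP2 (6.49 ± 0.86), TRDN (2.03 ± 0.15) and SOX2 (1.08 ± 0.15) rose and SERPINB1 (-3.63 ± 0.36) and LGALS1 (-2.20 ± 0.25) fell. In primitive streak-like cells HMX1 rose (2.28 ± 0.23), and MT1H (at least 255-fold lower), the caudal homeobox gene CDX4 (-7.44 ± 0.67) and TMEM88 (-5.05 ± 0.58) fell. DESeq2 called 104, 109, 322, 17, 30 and 20 genes in amnion-like, endoderm-like, fibroblast and mesoderm-like, hPGCLC-like, pluripotent and primitive streak-like, and primitive streak-like cells. With edgeR no gene was called in amnion-like cells once any CDKO line was left out. The same held in endoderm-like cells without any CTRL line or CDKO1105, and in fibroblast and mesoderm-like cells without CTRL1101 or CDKO1105.

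Stage comparisons in CTRL described the course of differentiation. From hESC to iMeLC 3603 genes rose and 3635 fell of 21230 tested (edgeR; median of all genes -0.08). The rule named the WNT agonist gene RSPO3 (4.22), the metallothionein MT1M (4.44), PITX1 (3.67), MFAP5 (3.60) and LYPD1 (3.47) among those that rose. Among those that fell it named LINC00599 (-4.13), the tryptophan-degrading enzyme gene IDO1 (-3.00), CRB2 (-2.98), AC091133.2 (-2.96) and MT1X (-2.69). The lowest mean level allowed by the rule was taken over all CTRL samples, D4 included. From hESC to iMeLC, RSPO3 went from 0.264 to 4.94 CPM, PITX1 from 0.296 to 3.77 CPM and CRB2 from 1.82 to 0.230 CPM. These genes were below that level at both stages and met it only through D4. SOX17 rose from 5.31 to 11.5 CPM (1.12, adjusted p = 0.0279), as did CDX2 (2.77), SP5 (3.47), GATA4 (1.24), FOXA2 (1.06) and LEF1 (1.77), while DPPA4 (-1.55) and KIT (-1.82) fell. POU5F1 (-0.19), SOX2 (-0.04), TBXT (0.50) and EOMES (0.61) did not pass. Without CTRL1101 the count of 7238 was 1812, and without CTRL1106 it was 2582. In CDKO 3604 genes rose and 3157 fell between these stages (of 19661), or 857 in all without CDKO1105 and 3932 without CDKO1312.

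From iMeLC to D4 5236 genes rose and 4673 fell in CTRL (median of all genes 0.07). By the rule, CGA, a hormone subunit gene, rose by 14.62, the galectin gene LGALS16 by 12.88, VTCN1 at least 3572-fold, RGS13 at least 4072-fold and AC015522.1 at least 2196-fold. CGA (617 ± 1065 CPM at D4) and LGALS16 (57.5 ± 96.5 CPM) had SDs above their means. SFTA1P (-8.51), JAKMIP2-AS1 (-8.06), AC091820.1 (-6.88), the caveolin gene CAV1 (-5.99) and MRGPRF (-5.79) fell most. Germ cell genes rose, with NANOS3 at 0.772 CPM in iMeLC and 35.0 CPM at D4 (5.50 ± 0.48, adjusted p = 9.35e-05), SOX17 (2.03) and PRDM1 (2.04), and 9 of 15 genes of germ cell specification rose and 2 fell (9 and 3 adjusted over the list alone). SOX2 fell from 391 to 8.58 CPM (-5.51) and POU5F1 from 596 to 214 CPM (-1.48), with 14 of 20 core pluripotency genes lower. Of 18 amnion genes 15 rose, of 15 mesoderm genes 15, of 10 BMP targets 10 and of 25 HOX genes 20, with TFAP2A (7.85), HAND1 (11.86), ISL1 (7.25), ID1 (2.26) and HOXB5 (9.01) as examples. Without CTRL1101 the count of 9909 was 6385, and without CTRL1106 it was 6059. In CDKO 5169 rose and 4616 fell, or 5134 in all without CDKO1105. There, 5 of 15 genes of germ cell specification rose and 3 fell, and 15 of 18 amnion genes, 13 of 15 mesoderm genes, 10 of 10 BMP targets and 13 of 24 HOX genes rose.

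Whether the change from iMeLC to D4 differed by genotype was tested for 21935 genes, and 2 were called with edgeR (2731 at an unadjusted p under 0.05; 434 with DESeq2, and 5 with the line as a replicate block). No gene was called with a stricter cell filter or without the HOX-high cluster. Without CTRL1101 the count was 377 and without CDKO1102 it was 11, and it was at most 3 without any other line. DNAJA4 was at 5.36 CPM in CTRL iMeLC and 4.45 CPM in CTRL D4, against 0.681 and 0.0232 CPM in CDKO (difference of log2 changes -4.55 ± 0.42, adjusted p = 0.000334). Without the HOX-high cluster the difference was -1.55 ± 0.59 (adjusted p = 0.379), and without the mixed cluster too it was gone (0.06 ± 0.75, adjusted p = 1.0), as DNAJA4 was then at 0.0261 CPM in CDKO iMeLC. CPN1, a carboxypeptidase subunit gene, was at 0.788 and 0.931 CPM in CTRL and at 0.0551 and 3.07 CPM in CDKO (5.47 ± 0.75, adjusted p = 0.0289), and at 5.44 ± 0.75 (adjusted p = 0.0602) without the HOX-high cluster and 5.40 ± 0.75 (adjusted p = 0.0599) with the stricter filter its fold was close to the same. With the line as a replicate block both stayed called (adjusted p = 0.0145 and 0.0350), and LFNG (1.83), MATK (2.57) and SERPINF2 (4.27) were added; all 5 fall outside the rule and were named after their values were seen. The germ cell genes NANOS3 (-2.49 ± 0.66, adjusted p = 0.160), SOX17 (-1.94, adjusted p = 0.207) and PRDM1 (-1.35, adjusted p = 0.199) and SOX2 (3.68, adjusted p = 0.178) did not pass. A lower rise of the germ cell genes in CDKO than in CTRL was thus not shown by this test.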

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

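The test behind this part was planned before the values were seen, and the genes it called were not. The change from iMeLC to D4 differed between CTRL and CDKO for 2 genes in the interaction test (edgeR quasi-likelihood). DNAJA4, a co-chaperone gene on chromosome 15 (78264086 to 78282196, overlapped by WDR61 on the opposite strand), had a difference of log2 changes of -4.55 ± 0.42 (adjusted p = 0.000334). It was at 6.17, 5.36 and 4.45 CPM in CTRL and at 0.327, 0.681 and 0.0232 CPM in CDKO at hESC, iMeLC and D4, so that it was low in CDKO at every stage. It stayed called in 11 of 14 alternatives, with adjusted p values from 4.03e-07 to 1.0. The difference was -1.97 ± 0.60 with the strict cell filter, -1.55 ± 0.59 without the HOX-high cluster and 0.06 ± 0.75 without the mixed cluster too. There the level in CDKO iMeLC was 0.0261 CPM, close to that at D4, so the call rested on transcripts of those cells at iMeLC. CPN1, a carboxypeptidase subunit gene, had a difference of 5.47 ± 0.75 (adjusted p = 0.0289). It was at 0.907, 0.788 and 0.931 CPM in CTRL and at 0.0700, 0.0551 and 3.07 CPM in CDKO, and stayed called in 7 of 14 alternatives (4.03e-07 to 0.179). Its difference was 5.40 ± 0.75 with the strict cell filter, 5.44 ± 0.75 without the HOX-high cluster and 5.35 ± 0.76 without the mixed cluster too (adjusted p = 0.0599, 0.0602 and 0.0794), so the fold stayed while the adjusted p rose past 0.05. Both genes have low counts. Another split of the same lines called 587 genes in this test (lines CTRL1101, CDKO1105 and CDKO1312 against the rest), against 2 for the real one; what this split reflects was not tested.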

How the results depend on the processing

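Alternatives that removed the HOX-high, mixed or endoderm-like clusters, or left called genes out of the clustering, were chosen after seeing the data. So was the removal of doublets, by the top 6% of scores for shares and by Scrublet's marks for gene tests. The rest were planned. For the main results 234 of 333 alternatives gave the same answer, 88 moved and 11 reversed, and the cause was not tested. DESeq2 called more genes in each comparison of genotypes: 2016 at hESC (1108 with edgeR), 956 at iMeLC (220), 497 at D4 (7), 15 and 434 for the interactions at iMeLC and D4 (0 and 2), and in D4 classes 104 in amnion-like (5), 109 in endoderm-like (5), 322 in fibroblast and mesoderm-like (30), 17 in hPGCLC-like (3), 30 in pluripotent and primitive streak-like (15) and 20 in primitive streak-like cells (13). The median of all genes from iMeLC to D4 was 0.19 in CTRL (0.07 with edgeR) and 0.11 in CDKO (0.06) with DESeq2, which also tested more genes. It was 0.05 and 0.04 with the size factors of DESeq2 alone and 0.18 and 0.22 with the low-count filter alone left out, so the size factors did not raise it. Without the filter on low counts the numbers were 494 at iMeLC, 11 at D4 and 90, 278, 252, 191, 326 and 298 in the same 6 classes. With all 18 samples in a single fit they were 196 at hESC and 732 at D4. Without the HOX-high and mixed clusters 708 genes were called at hESC, and 531 without the endoderm-like cluster too. The interaction at D4 had 0 calls with the strict cell filter, without the HOX-high cluster and without the mixed cluster too, where CPN1 kept its fold (5.35 to 5.44 against 5.47, adjusted p = 0.0599 to 0.0794) and DNAJA4 did not, and 5 with the replicate block. The block moved no other count by more than 1.5 times, and 26 of 654 called gene results were weaker and 15 of 98 not called passed with it. With Leiden resolution 1.0 the calls were 9 in endoderm-like, 54 in fibroblast and mesoderm-like and 32 in pluripotent and primitive streak-like cells.

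The share of fibroblast and mesoderm-like cells (CDKO minus CTRL -16.5 points) was 8.74 with fewer variable genes and 4.30 with all barcodes; that of primitive streak-like cells (-0.345) was 4.12 with Leiden resolution 0.25 and 0.244 with the strict filter. Camera called 9, 12 and 10 lists at hESC, iMeLC and D4. The numbers were 0 at each stage with an estimated correlation, 3 at hESC and 6 at iMeLC without the clusters (of the 6, S phase was not among the 12), and 4 at iMeLC and 1 at D4 with fry. For 764 called gene results, 7758 of 9004 alternative fits gave the same call, 1239 were weaker and 7 reversed; for 327 results not called, 207 of 4751 fits passed. The reversed fits were FGF17 (-0.69), GATA6 (-0.046) and PRRX1 (-0.29) at iMeLC without the HOX-high, mixed and endoderm-like clusters, NR2F2 in CDKO from iMeLC to D4 (-1.31), at 0.35 with the strict filter, 0.39 without the HOX-high and 1.18 without the mixed cluster too, and DNAJA4 in the interaction without the HOX-high and mixed clusters (0.055).

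Leaving out each line in turn, counts ran from 182 to 1225 at hESC (CDKO1105 lowest; 337 without CTRL1106, 608 without CDKO1102, 274 without CDKO1312), 60 to 181 at iMeLC (CDKO1105 lowest; 106 without CTRL1106, 67 without CDKO1312) and 0 to 17 at D4 (0 without CTRL1101, CDKO1102 or CDKO1105, 17 without CTRL1106, 4 without CDKO1312). From hESC to iMeLC they ran from 1812 (without CTRL1101) to 6003 in CTRL (2582 without CTRL1106) and from 857 (without CDKO1105) to 5851 in CDKO (3932 without CDKO1312). From iMeLC to D4 they ran from 6059 (without CTRL1106) to 8293 in CTRL (6385 without CTRL1101) and from 5134 (without CDKO1105) to 8473 in CDKO. The interaction at D4 had 1 to 377 (377 without CTRL1101, 1 without CTRL1106 or CTRL1109, 11 without CDKO1102). Amnion-like cells had 0 to 40 (40 without CTRL1106, 3 without CTRL1101, 0 without CDKO1102, CDKO1105 or CDKO1312), endoderm-like 0 to 5 (0 without CTRL1101, CTRL1106, CTRL1109 or CDKO1105, 1 without CDKO1312), fibroblast and mesoderm-like 0 to 66 (66 without CTRL1106, 9 without CTRL1109, 7 without CDKO1102, 2 without CDKO1312, 0 without CTRL1101 or CDKO1105), hPGCLC-like 0 to 21 (21 without CTRL1106, 5 without CTRL1101, 6 without CTRL1109, 0 without CDKO1102 or CDKO1105), pluripotent and primitive streak-like 10 to 120 (120 without CTRL1101, 59 without CTRL1106, 33 without CDKO1105) and primitive streak-like 1 to 130 (130 without CTRL1101, 38 without CTRL1106, 2 without CDKO1105, 1 without CDKO1312). In the last 2 classes without a CTRL line, and in hPGCLC-like cells without a CDKO line, 1 library stood for that group and the spread came from the other group alone, so these counts test little. The share difference of hPGCLC-like cells stayed between -9.29 and -5.48 points and that of the marker rule between -5.85 and -3.96. Pluripotent and primitive streak-like shares ran from -2.61 (without CDKO1312) to 10.4, and primitive streak-like shares from -6.10 (without CDKO1312) to 2.85 (without CDKO1102). TET1 at hESC ran from -0.053 (without CTRL1101) to 0.064.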

Other observations

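The tests on neighbouring genes and on HOX transcripts outside the HOX-high and mixed clusters were written before their values were seen, and all other tests in this part were chosen after seeing the result. Beside the genes that fell, a few rose from near silence in CDKO; these were chosen after their values were seen. TRIM4, a ubiquitin ligase gene (chromosome 7, 99876958 to 99919600), was at 0.0366 CPM in CTRL and 3.73 CPM in CDKO at hESC (6.64 ± 0.30, adjusted p = 9.69e-05), at 0.0711 and 3.90 CPM at iMeLC (5.72 ± 0.33, adjusted p = 0.000371) and at 0.575 and 7.77 CPM at D4 (3.75, adjusted p = 0.112). HMX1, a homeobox gene, was at 4.06 at hESC and 3.19 at iMeLC. Among the genes that fell at both stages were the DNA sensor gene CGAS (-5.92 and -7.47), the interferon-induced MX2 (-5.21 and -6.33), and the germline genes TDRD5 (-4.31 and -5.29) and AURKC (-2.12 and -2.48).

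In all, 71 genes were called with a log2 fold change of -2 or lower at both hESC and iMeLC, with medians of -3.94 and -4.61 (-3.94 and -4.60 with genes at 0 in CDKO at their bounds), and 8 genes were called 2 or more higher at both. Without the HOX-high, mixed and endoderm-like clusters the median of the set at hESC was -4.01. Those clusters held 12.6%, 14.2% and 8.34% of CDKO hESC cells, too few for their removal to undo falls of this size. Clusters that were kept also differed in share. An iMeLC cluster led by MT1H, MT1G and LGALS1 had 123, 1670 and 688 cells in the CTRL lines and 9, 5 and 6 in the CDKO lines. Unequal shares of cells were therefore not excluded by this removal. Loss of large regions around most of these genes does not explain the set. The 2054 tested genes within 1 Mb of them had a pooled median of -0.057 at hESC. That median cannot exclude small losses, or losses at a few of the genes. At D4, 57 of the 63 genes tested had all CDKO lines below all CTRL lines; they were chosen for low values in the same lines at the earlier stages, so no chance level applies. Both a lasting effect of the missing catalytic domain and a separate history of the CDKO lines could leave such a pattern, and the 57 genes cannot tell them apart, as each genotype has its own lines and DNA methylation was not measured here.

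The HOX list was called higher in CDKO hESC and iMeLC by camera. No HOX gene passed over all genes at iMeLC, and neither list call held with an estimated correlation. A larger share of HOX-high cells could be the cause. Those and the mixed cells held 75% of HOX UMIs at hESC and 66.2% at iMeLC. Outside them the summed HOX level still had a log2 ratio of 1.91 at hESC (2.23 ± 0.78 against 8.40 ± 8.87 CPM, overlapping, exact permutation p = 0.20) and 1.26 at iMeLC (5.01 ± 2.21 against 12 ± 9.80 CPM, exact permutation p = 0.20), with a spread too wide to decide. In all cells the ratios were 1.71 and 1.78. By the rule written beforehand, ratios kept to this extent would have counted against this cause. The demand that the lines not overlap was not part of that rule. Since they did overlap, no conclusion was drawn. At iMeLC the HOX list's median went from 1.61 in all cells to 0.13 outside them, over the 11 genes still measured. Human fibroblasts could not be excluded as HOX-high cells. Of 11 fibroblast genes 6 were at or below their level in the other clusters, among them THY1 (173 against 397 CPM) and COL1A2 (37.4 against 50.1 CPM), but DCN, LUM and POSTN of these were under 1 CPM in both, and COL3A1 (24.9 against 0.137 CPM), FBN1 (34.3 against 4.56 CPM) and COL1A1 (221 against 52.2 CPM) were higher. Cells of another species could give reads at gene copies such as H3F3C (423-fold above the other clusters), but no other genome was used here and this remained open.

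The first 30 Mb of chromosome 12 were higher in CTRL1109 at all stages. Scaling of libraries does not explain it, since the rest of the chromosome was shifted by -0.10 at most, and neither do a few abundant genes, since at least 94.7% of the region's genes lay above 0 at each stage. Extra copies of the region in this line, with a lowest median shift of 0.72, would fit the data, and DNA was not measured here. No other biological explanation was tested.

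The 6 lines can be split into 3 and 3 in 10 ways, the real one included, too few for a share under 0.05. The split by genotype was the 1 of 10 with the most calls at hESC (1108, highest other 1), iMeLC (220, highest other 0) and D4 (7, highest other 0). The same held within amnion-like (5, highest other 3), endoderm-like (5, highest other 1) and fibroblast and mesoderm-like cells (30, highest other 1). The interaction at iMeLC had 0 calls in all 10 splits, and that at D4 was matched or passed in 2 of 10, with 587 calls in the highest. For the 4 stage comparisons within a genotype, the 6 samples of the 2 stages were split in the same number of ways, 4 of which part every pair of samples of a line; the real split was the 1 with calls (highest other 0).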
